A study of Mus musculus with 6 samples.

How the data were processed

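The series holds 6 RNA-seq libraries of mouse cornea, 3 from Muc13 knockout and 3 from wild-type C57BL/6 males aged 6 weeks, grouped by the genotype in the labels. Total RNA was used with an mRNA library kit, per the labels' protocols; the aligner, the counting program, the annotation release and the use of strand are not given in the sources used here. The submitters' processing notes name the genome build GRCm38 (mm10). The authors deposited 1 table of 18227 genes with 4 kinds of value per library.

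The first kind is expected counts (estimated reads per gene), which the authors deposited without normalization; between 1094 and 1217 genes per library were not whole. The second is a signal of scaled counts: per the values in the deposited table, it equals the expected counts rounded up and divided by 1 size factor per library in all 18227 genes, and those factors match DESeq2's median-of-ratios factors. The TPM values the authors deposited are scaled to the same total in every library, and the FPKM values the authors deposited are a constant multiple of TPM within each library. Tests used the expected counts, rounded to whole numbers. The 8 average columns were not used. Because whole-tissue counts are relative, a library rich in retina or lens RNA holds fewer counts of all other genes, and TMM scaling corrects this only on average.

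Gene identifiers were matched to GENCODE M21 on GRCm38, the same build as the submitters' notes; 18181 of 18227 matched and 46 did not. Coordinates are 1-based. Genes whose counts are not whole in any library are called genes with shared reads.

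Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main test was edgeR's quasi-likelihood test with genotype as the only term, TMM scaling, the filterByExpr filter and robust dispersion, with Benjamini-Hochberg adjusted p under 0.05. The filter kept 14983 genes, Muc13 not among them, and removed 3244. CPM are TMM-scaled, and log2 CPM for list tests, correlations and principal components used a prior count of 2. The square root of the common dispersion was 0.585. SEs of log2 fold changes are the fold change divided by the square root of F. Another scaling, library size alone, moves the median log2 fold change of all genes to 0.19, against 0.02 with TMM. Totals of 1.41e+07 to 1.55e+07 counts put 3 counts, the limit that a count of 0 allows, at 0.185 to 0.233 CPM. Intervals of 95% are exact and, like that limit, cover counting error only.

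Before the data were examined, 53 gene lists were fixed, covering cornea cell types, other eye and orbital tissues, blood and immune cells, mucins, inflammation, metabolism, growth pathways and technical checks. Of these, 47 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, 2 were read as values only and 4 had too few tested members. Muc13 is in no list. The list counts adjusted over the list alone use the p-values of the main test. They are not adjusted for the number of lists, and 5 of the 47 lists held a member that passed in this way. For such members, fell and rose refer to this adjustment only.

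Named genes followed a rule fixed at the same time. Muc13, Tgm1, Krt12, Muc1 and Muc4 are always named. Fewer than 6 genes passed, so the 12 genes with the smallest p in each direction were taken among those whose groups do not overlap, with a mean of at least 1 CPM and a symbol that is not a predicted model. Up to 4 members with the smallest p came from each list with a call, of which 2 at most are printed for lists other than interferon response, up to 2 abundant members from other tissue lists with no call, and the 3 genes with the most counts. Gm14440 falls outside the rule and was chosen after its values were seen. Not every gene that the rule picks is printed. Muc16, which the rule also names, was not analysed here. The sex-linked check genes are given together and not by name.

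Mean chi-square values per gene between libraries were 43.5 to 551, far above 1, so no library repeats another. The analysis was tested on simulated counts for this comparison. With the spread of these libraries and 200 of 14849 genes changed, 0% of the 2-fold and 7% of the 4-fold changes were recovered with 0 false calls, a list of 50 shifted genes was found (adjusted p = 0.000302) and 0 of 9 unshifted lists were called. With a coefficient of variation of 0.2 and 14916 genes, 74% and 100% were recovered, with 15 false calls. Simulated genes were drawn independently, while the estimated correlation within the interferon-response list of the real data was 0.394. The 0 of 9 unshifted lists therefore does not show how often camera calls lists wrongly in these libraries.

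Alternatives fixed in advance were DESeq2 size factors, library size alone, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the DESeq2 Wald test, limma-voom with and without sample quality weights, the replicate number as a block, leaving out mitochondrial, haemoglobin and muscle genes, leaving out each library in turn, stricter thresholds and the estimated correlation. Added after seeing the data were a comparison without WT 1 and WT 2, the retina content as a covariate, and the interferon-response list without its 1 member near Muc13. A planned comparison with the authors' own fold changes and a test of annotation terms were not run, since neither was analysed here.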

Results

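RNA was sequenced from whole corneas of 6-week-old male C57BL/6 mice, 3 samples from mice lacking Muc13, a transmembrane mucin of epithelial surfaces, and 3 from wild-type mice of matched age and sex. The libraries are called KO 1 to 3 and WT 1 to 3. Total expected counts were 1.41e+07, 1.48e+07 and 1.45e+07 in KO 1 to 3 and 1.55e+07, 1.51e+07 and 1.49e+07 in WT 1 to 3. Of the 18227 genes in the table, 16978, 17094 and 17024 were above 0 in the knockout libraries and 15812, 16502 and 17082 in the wild-type libraries. The question put by the design was which genes differ in the cornea between the genotypes. The labels do not say whether each sample came from 1 mouse or from several, and p-values of single genes measure the spread between these samples. Camera p-values with the preset correlation compare the genes of a list with other genes and take them as nearly independent. Fisher's exact test likewise counts genes, not samples.

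Muc13 itself (ENSMUSG00000022824, protein coding, chromosome 16, 33794037 to 33819934 in GRCm38) was close to the detection limit in every library. It had 9, 4 and 2 counts in KO 1 to 3 and 18, 21 and 9 counts in WT 1 to 3. The means were 0.330 ± 0.242 CPM (counts per 1e+06 counts) in the knockout group and 1.15 ± 0.513 CPM in the wild-type group (SD, n = 3 each). Pooled over libraries, the knockout level was 0.328 of the wild-type level (95% exact interval 0.170 to 0.595, counting error only). KO 1, at 0.597 CPM (0.273 to 1.13), lay above WT 3, at 0.561 CPM (0.257 to 1.07), so the groups overlapped. The exact two-sided permutation p was 0.2, where 0.1 is the smallest that 3 against 3 allows. In the edgeR fit with no filter on low counts the log2 fold change was −1.78 (SE 0.748, adjusted p = 0.540). The part of the gene that was deleted is not given in the sources used here, and reads can remain from other exons.

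The 6 corneas differed first of all in how much RNA of neighbouring eye tissues they held. For retina RNA this was partly confounded with genotype, since the libraries with little of it, WT 1 and WT 2, were wild type. Members of the retina list summed to 45609, 26617 and 28923 CPM in KO 1 to 3 and to 30187 CPM in WT 3, but to 504 and 739 CPM in WT 1 and WT 2. The lens crystallin Cryaa ran from 4 counts in WT 1 and 326 in KO 3 to 306547 in WT 3 and 459033 in KO 2. Krt12, the keratin of the corneal epithelium and the gene with the most counts, took 3.49% and 2.90% of the counts in WT 1 and WT 2, 1.36%, 1.16% and 1.08% in KO 1, KO 2 and WT 3, and 0.151% in KO 3. Skeletal muscle genes summed to 7760 and 6524 CPM in WT 1 and WT 2 and to between 321 and 1910 CPM in the other libraries. The iris, ciliary body and melanocyte list was highest in KO 3, at 8166 CPM, and lowest in WT 1, at 49.9 CPM.

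**Figure D1:**
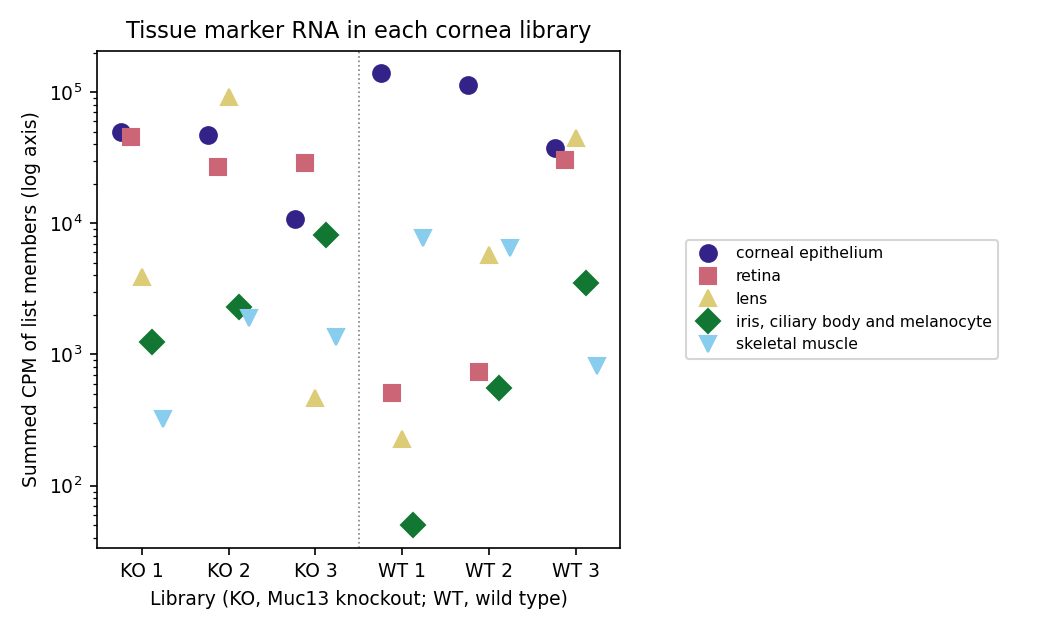
Summed CPM of the members of 5 tissue lists (log axis) in each of the 6 libraries, with 1 point per list and library, shifted sideways for legibility. WT 3 lies with the knockout libraries in retina RNA, at 30187 CPM, while WT 1 and WT 2 are at 504 and 739 CPM.

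The first principal component of log2 CPM held 83.3% of the variance and set WT 1 and WT 2 apart from the other 4 libraries. Across genes, WT 3 correlated more closely with the knockout libraries (Pearson r 0.966, 0.977 and 0.926) than with WT 1 and WT 2 (0.687 and 0.773). Genes are not independent replicates, and these correlations describe the libraries only. Each of the 4 Y-linked check genes was present in every library, at 17.0 to 95.8 CPM. Nnt, which is partly deleted in the C57BL/6J substrain, had 47 to 104 counts per library in both genotypes.

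Interferon-response genes were lower in all 3 knockout corneas than in all 3 wild-type corneas. Of the 49 members of this list, 41 lay below every wild-type library in every knockout library, and the median log2 fold change was −1.70. The antiviral 2'-5' oligoadenylate synthetase Oas3 was at 10.6 ± 2.16 CPM against 67.4 ± 24.3 CPM in the wild type (SD, n = 3 each). Isg15, a ubiquitin-like modifier, was at 20.8 ± 5.02 against 91.7 ± 26.2 CPM, and the interferon-induced GTPase Iigp1 was at 6.19 ± 3.08 against 46.4 ± 3.62 CPM.

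Adjusted over the list alone, 37 of the 49 interferon-response genes fell, 0 rose and 12 did not pass; adjusted over all genes tested, 0 passed. The log2 fold changes were −2.67 for Oas3, −2.14 for Isg15, −1.81 for Dhx58 (an RNA sensor of the RIG-I family), −2.90 for Iigp1, −1.58 for Irf7 (a transcription factor of the interferon response) and −2.37 for Rtp4, an interferon-induced inhibitor of virus replication, with SEs of 0.338, 0.293, 0.250, 0.414, 0.233 and 0.366. The mean log2 CPM of the list was 3.42, 3.58 and 3.98 in KO 1 to 3 and 5.26, 5.79 and 5.12 in WT 1 to 3. The difference of −1.73 had an exact two-sided permutation p of 0.1, the smallest possible with 3 against 3. WT 3, whose retina RNA was at the knockout level, had the wild-type level of these genes: against WT 3 alone the medians were −1.81, −1.58 and −1.13 for KO 1 to 3, with 46, 47 and 47 of the 49 members lower. The list passed camera with the preset correlation (adjusted p = 8.25e-30) and did not pass with an estimated one (adjusted p = 0.757 with an estimated correlation). Fry, which asks whether the members move one way, gave an adjusted p = 0.128. Counts that are not whole, as for Oas3, mark reads shared with similar genes in 14 of the 49 members.

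**Figure D2:**
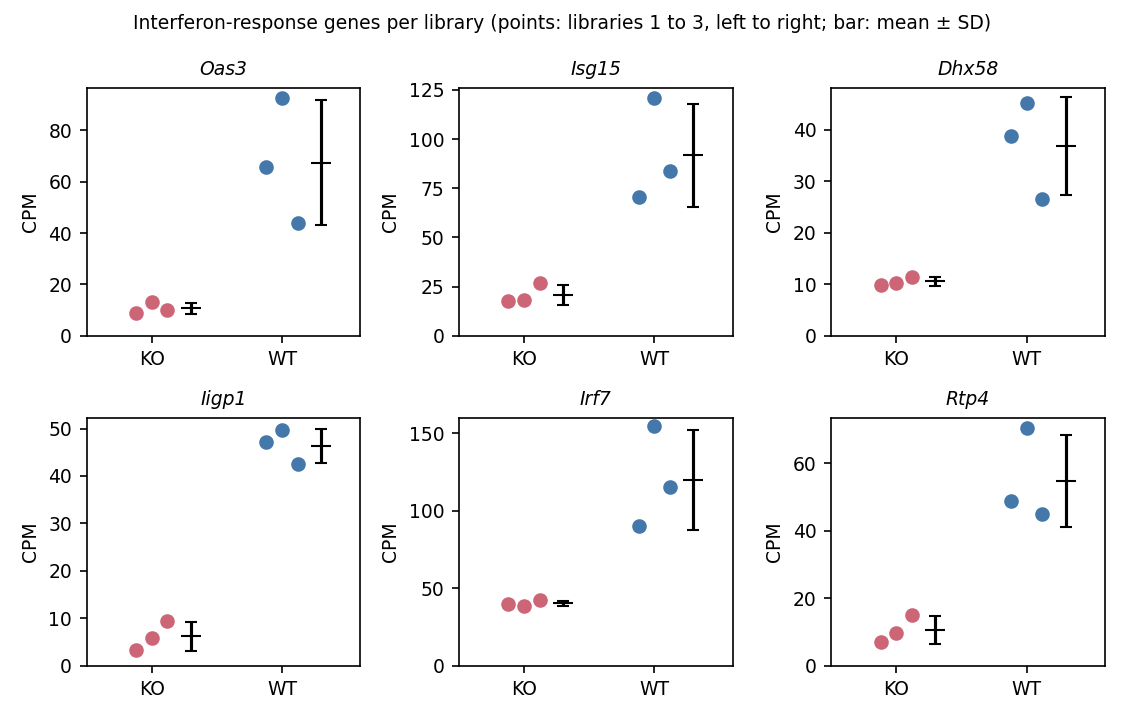
CPM of 6 interferon-response genes (linear axes from 0) in the 3 knockout and 3 wild-type libraries, each point a library in the order 1 to 3, with the mean and SD of each group beside the points. For Irf7 the knockout libraries lie at 38.5 to 42.1 CPM and the wild-type libraries at 90.2 to 154 CPM.

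Over all 14983 genes tested, 0 passed an adjusted p of 0.05 with edgeR's quasi-likelihood test, and the smallest adjusted p was 0.501. At an unadjusted p under 0.05 there were 656 genes, 108 higher and 548 lower in the knockout. This is a smaller share of the genes tested than the 0.05 that such a threshold gives when no gene differs. DESeq2 gave 72 genes, 13 higher and 59 lower, and 30 of the lower ones were in the interferon-response list. The groups did not overlap in 1531 genes, or 10.2%, where chance gives 10%. Without WT 3 the edgeR count was 5166, of which 3205 were higher and 1961 lower in the knockout, and 31 retina genes were among the higher ones. The count at an unadjusted p under 0.05 was 7671 without WT 3 and 156 to 285 without any other single library. Medians given below without WT 1 and WT 2, a setting chosen after seeing the tissue content, set the 3 knockout libraries against WT 3 alone, so they hold no spread between wild-type samples and are given as values, not as tests.

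The genes with the smallest p in each direction did not pass the adjustment over all genes, and all had an adjusted p of 0.501. Of the 12 with lower values in the knockout, 7 were members of the interferon-response list. The others were Gbp10 (log2 fold change −3.04, SE 0.422), a guanylate-binding protein; Slfn2 (−2.05, SE 0.312); Apol9a (−2.07, SE 0.313); Ddx60 (−2.09, SE 0.318), an antiviral helicase; and Ide, the insulin-degrading enzyme. Ide (chromosome 19, 37268743 to 37337852) was at 72.8 ± 6.35 CPM in the knockout and 163 ± 13.5 CPM in the wild type (log2 fold change −1.16, SE 0.166). That its groups do not overlap follows from the rule that chose it. Gbp10 and Apol9a share reads with near relatives and are uncertain as single genes.

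Among the 12 with higher values, the macrophage and gland lysozyme Lyz2 was at 104 ± 21.8 CPM in the knockout and 32.4 ± 9.11 CPM in the wild type (log2 fold change 1.68, SE 0.282). Prb1, which encodes a proline-rich protein of the salivary type (chromosome 6, 132206795 to 132210521), had 135, 104 and 34 counts in KO 1 to 3 and 0 in each wild-type library, at least 25.8-fold higher against a floor of 3 counts per library. Its neighbour Prpmp5 was at 7.20 ± 2.57 against 0.0623 ± 0.108 CPM, with shared reads. The immediate early genes Fosb, Egr2 and Egr3 had log2 fold changes of 3.04, 4.09 and 3.72 (SE 0.570, 1.20 and 1.08), and ranged in the knockout from 8.16 to 28.3 CPM for Fosb and from 1.33 to 31.4 CPM for Egr2, whose log2 fold change was 2.59 without KO 3. The macrophage elastase Mmp12 (2.30, SE 0.589), the scavenger receptor Stab2 (1.77, SE 0.556), Rimbp3 (3.14, SE 0.743), Pnrc1 (0.82, SE 0.258) and the histone genes H2bc4 (0.72, SE 0.220) and H2aw (1.30, SE 0.396) made up the rest, the 2 histone genes with shared reads.

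Antigen presentation genes lay on the same side as the interferon-response genes, with a median log2 fold change of −1.07 over 27 members (camera adjusted p = 6.54e-07; adjusted p = 0.757 with an estimated correlation). The peptide transporter Tap1 fell (−1.74, SE 0.310; adjusted over the list alone, adjusted p = 0.0445), the other 26 did not pass, and H2-T23, a class I molecule with shared reads, was at −1.63 (SE 0.358). The median was −0.32 without WT 1 and WT 2 and −0.62 without WT 2. Among 22 inflammatory cytokines and chemokines (median −0.02, camera adjusted p = 0.834), the interferon-induced chemokine Cxcl9 fell and was the 1 member past the test adjusted over the list alone (adjusted p = 0.0438). It had 22, 20 and 13 counts in WT 1 to 3 and 0 in each knockout library, at least 6.49-fold lower against the same floor. Ptgs2, the inducible cyclooxygenase, was at 2.72 (SE 0.933) and did not pass. Pattern recognition and NF-kB genes had a median of −0.42 (camera adjusted p = 0.00353; adjusted p = 0.757 with an estimated correlation), with Tlr3 at −0.96 (SE 0.359) and the inflammasome adaptor Pycard at −1.46 (SE 0.591), and a median of 0.04 without WT 1 and WT 2. Its median was −0.64 without WT 3 and −0.22, with no call, without WT 2.

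Markers of macrophages and dendritic cells lay higher in the knockout, with a median of 0.56 over 25 members (camera adjusted p = 0.00836; adjusted p = 0.757 with an estimated correlation). Lyz2 rose (adjusted over the list alone, adjusted p = 0.0300), 24 members did not pass, and Ms4a7 was at 1.18 (SE 0.426). The median was 0.52 without WT 1 and WT 2, but it was 0.15 without WT 1, and the list did not pass without KO 3 (0.30) or without WT 3 (0.60). In the neutrophil list (11 members, median 1.22, camera adjusted p = 0.236) 6 members lay above 0 and 5 below. Its summed CPM was 318, 230 and 141 in KO 1 to 3 and 377, 471 and 168 in WT 1 to 3. The myeloid lectin Clec4d rose (3.29, SE 0.504, adjusted p = 0.00808 over the list alone) from 0.0912 ± 0.0292 to 0.974 ± 0.0646 CPM. It had only 1, 1 and 2 counts in WT 1 to 3. Chil1 was at 1.87 (SE 0.863). Complement genes had a median of 0.60 (camera adjusted p = 0.00811; adjusted p = 0.757 with an estimated correlation), with properdin, Cfp, at 0.91 (SE 0.439) and the receptor C3ar1 at 1.02 (SE 0.517); the median was 0.27 without WT 1 and WT 2, and the list did not pass without WT 3 (0.73). Red blood cell genes had a median of 1.68 over 7 members (camera adjusted p = 0.00296; adjusted p = 0.757 with an estimated correlation), with the alpha globin copies Hba-a1 and Hba-a2, which share reads, at 1.88 and 1.85 (SE 0.614 and 0.578).

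Epithelial gene groups lay lower in the knockout on average, with their highest summed CPM in WT 1 and WT 2, the libraries with little retina RNA; for the basement membrane list WT 3 was close to WT 1 (6494 and 6753 CPM). The corneal epithelium list had a median of −1.43 over 23 members (camera adjusted p = 0.00186), with the desmosomal protein Perp at −1.75 (SE 0.827) and Trp63, a transcription factor of stratified epithelium, at −1.93 (SE 0.917). Its summed CPM was 138838 and 112624 in WT 1 and WT 2, 37393 in WT 3, and 49911, 46811 and 10714 in KO 1 to 3. Epithelial junctions (median −1.20, camera adjusted p = 8.63e-06; Gjb2 −0.90 and Epcam −2.04), cornified envelope and keratinisation (−1.03, 0.00802; Krt16 −3.45 and Krt1 −1.07) and the basement membrane and hemidesmosome (−0.72, 0.00144; Lamb1 −1.01) also passed. So did the EGF receptor family and ligands (−0.61, 0.0107; Epgn −2.18 and Spred1 −0.52) and lipid and cholesterol synthesis (−0.74, 8.63e-06; Mvk −1.05 and Elovl6 −1.20). Each had an adjusted p = 0.757 with an estimated correlation. Without WT 1 and WT 2 the medians were −0.02 for the corneal epithelium, −0.04 for junctions, 0.17 for the cornified envelope, −0.22 for the basement membrane, 0.07 for the EGF receptor family and −0.03 for lipid synthesis. Leaving out KO 3 took the call from the corneal epithelium (−0.97) and the EGF receptor family (−0.40) and moved junctions to −0.76; the EGF receptor family did not pass without WT 2 either (−0.45), and the basement membrane was at −1.16 without KO 2.

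In summed CPM, cell proliferation and cytosolic ribosome genes were likewise highest in WT 1 and WT 2, and glycolysis genes lowest, while oxidative phosphorylation genes were highest in WT 1 and higher in KO 3 than in WT 2. Cell proliferation genes had a median of −1.59 over 50 members, all with a log2 fold change below 0 (camera adjusted p = 2.10e-14), with the centromere histone Cenpa at −1.77 (SE 0.545) and the mitotic transcription factor Foxm1 at −1.51 (SE 0.469). Their summed CPM was 2074 and 1720 in WT 1 and WT 2, 700 in WT 3, and 727, 768 and 430 in KO 1 to 3. Cytosolic ribosome genes had a median of −0.80 (camera adjusted p = 2.76e-12; Rpl38 −1.03 and Rpl7l1 −0.65), and oxidative phosphorylation genes one of −0.28 (0.000432; Ndufs4 −0.68 and Ndufa8 −0.52). Glycolysis genes had a median of 0.63 (0.00893), although the members with the smallest p, Ldhb at 1.44 and Pfkm at −0.57, went opposite ways. Oxidative phosphorylation had an adjusted p = 0.799 with an estimated correlation, and the other 3 an adjusted p = 0.757 with an estimated correlation. Without WT 1 and WT 2 the medians were −0.25, 0.10, 0.12 and −0.01 in that order. Oxidative phosphorylation was at −0.0254, with no call, without WT 1, at −0.18 without KO 1 and at −0.45 without WT 3. Glycolysis was at 0.40, with no call, without WT 2 and at 1.04 without WT 3, and the ribosome at −0.44 without WT 1. Ldhb ran from 0.80 without KO 3 to 2.12 without WT 3, Ndufs4 from −0.41 without WT 1 to −0.92 without WT 3, and Ndufa8 from −0.32 to −0.72 in the same fits.

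**Figure D3:**
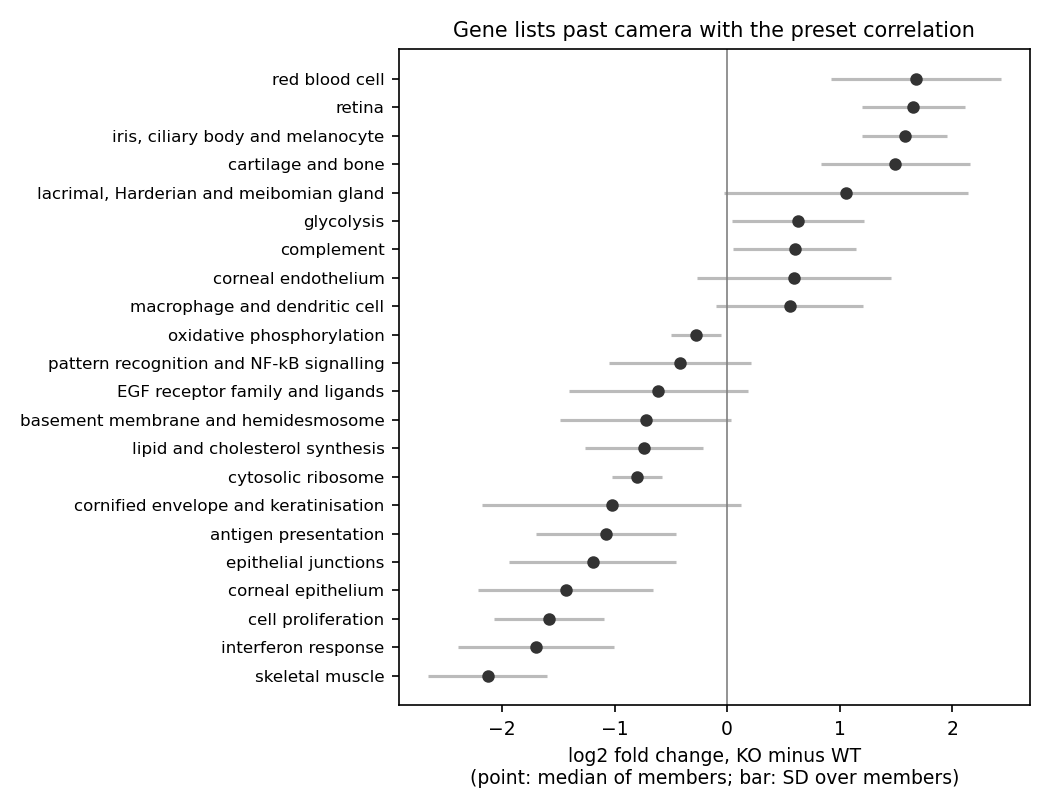
Median log2 fold change (knockout minus wild type) of the 22 gene lists past camera with the preset correlation of 0.01, 1 point per list, with bars for the SD over members. The medians run from −2.13 for skeletal muscle to 1.68 for red blood cells, and the interferon-response list is at −1.70; 0 of the 22 pass with an estimated correlation (smallest adjusted p = 0.757) and 0 by fry.

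Lists of other eye and orbital tissues also differed in level between libraries. Retina genes had a median of 1.65 over 31 members (camera adjusted p = 1.03e-09), led by the pigment epithelium enzymes Rpe65 (3.48, SE 1.42) and Lrat (3.00, SE 1.19). The iris, ciliary body and melanocyte list was at 1.58 (0.00127; Wfdc1 1.46 and Mitf 1.65), cartilage and bone at 1.496 (0.00311; Sp7 1.82 and Col9a3 2.12), and lacrimal, Harderian and meibomian gland genes at 1.06 (0.0353; Mogat1 2.08 and Awat2 1.06). Skeletal muscle was at −2.13 (9.87e-07; Myh1 −2.58, with shared reads, and Tnnc1 −2.27), and the corneal endothelium list at 0.59 (0.0410), where Grhl1 and Foxc1, its members with the smallest p, were at −1.23 and −0.96. Corneal endothelium had an adjusted p = 0.758 with an estimated correlation, and the other 5 an adjusted p = 0.757 with an estimated correlation. Without WT 1 and WT 2 the medians were 0.10, 0.31, 0.51, 0.47, 0.66 and −0.15. Leaving out WT 3 alone moved retina to 7.30, iris to 3.84, cartilage and bone to 2.97, glands to 2.21 and corneal endothelium to 2.05. Retina was at 1.07 without WT 1 and 1.09 without WT 2, iris at 0.54 without KO 3, and cartilage and bone at 0.82 without KO 3 and 0.91 without WT 1. Members moved with their lists between the fits without KO 3 and without WT 3: Mitf from 0.66 to 3.14, Wfdc1 from 0.70 to 2.19, Col9a3 from 1.28 to 3.85 and Mogat1 from 1.66 to 3.49. Glands did not pass without KO 1 (0.91), KO 3 (0.78) or WT 2 (0.62), nor corneal endothelium without KO 2 (0.62) or WT 1 (0.28), and neither passed with library size alone (1.19 and 0.70).

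Mucin genes other than Muc13 did not pass as a list, with a median of −0.39 over 11 members (camera adjusted p = 0.874), nor did the enzymes of mucin O-glycosylation (−0.05, 0.622). Muc4 was at 701 ± 650 CPM in the knockout and 1421 ± 712 CPM in the wild type, and Muc1 at 18.4 ± 7.56 and 24.1 ± 19.8 CPM (SD, n = 3 each). Their log2 fold changes were −1.02 (SE 0.968, adjusted p = 0.555) and −0.39 (SE 0.648, adjusted p = 0.697); Muc4 ranged from −1.996 without KO 1 to −0.50 without KO 3. Tgm1, a transglutaminase of the epithelial surface, was at 0.40 (SE 0.417, adjusted p = 0.576), Krt12 at −1.70 (SE 1.07), Aldh3a1, a corneal crystallin, at −1.67 (SE 1.01), mt-Co1 at −0.30 (SE 0.736) and Cryaa at 0.68 (SE 2.98).

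Of the 47 lists tested, 22 passed camera with the preset correlation, 13 lower and 9 higher in the knockout; 0 passed with an estimated correlation and 0 by fry. The lists named here that did not pass also included keratocyte and stromal matrix (median 0.26, adjusted p = 0.531), lens (1.05, 0.640), mitochondrially encoded genes (−0.11, 0.408), immediate early and dissociation stress genes (0.30, 0.1997) and genes near Muc13 (−0.07, 0.231). Immediate early genes passed with the retina covariate (0.86), without KO 1 (0.42) and without WT 2 (0.54), and were at 0.86 against WT 3 alone (adjusted p = 3.05e-15 to 0.839 over all alternatives). Genes near Muc13 passed in 1, without KO 1, at −0.09 (adjusted p = 0.0459 to 0.758 over all alternatives). The median and the camera test differed in sign for limbal and conjunctival epithelium (−0.07, 0.944), the Wnt pathway (0.03, 0.640) and the Notch pathway (0.00, 0.485). The medians of the other 13 lists lay between −0.62 and 0.95, and their smallest camera adjusted p was 0.0582.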

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

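The comparisons without WT replicates 1 and 2, with the retina content as a covariate, and with the shortened interferon list were chosen after seeing the data. The first sets the 3 knockout libraries against WT 3 alone, so its values describe 1 wild-type library. Its calls are not read as evidence, and the label of that library is itself open. With the retina covariate the result also rests largely on WT 3, since retina RNA was low only in WT 1 and WT 2. The edgeR count of genes was 0 under every alternative except the DESeq2 Wald test (72), limma-voom with sample quality weights (8118, where WT 3 had a weight of 0.154 and WT 2 one of 4.73) and leave-one-out, which ran from 0 to 5166, the latter without WT replicate 3; 69 of the 72 DESeq2 genes were among those 5166. The removal of WT 3 leaves 2 wild-type libraries, both poor in retina RNA. The count of shifted lists was 22, 16 to 26 in the other settings (15 against WT 3 alone) and 0 with an estimated correlation. The interferon-response list kept its direction and its call throughout, with medians from −2.09 to −1.34, except for the call with an estimated correlation (median −1.70, adjusted p = 0.757); without its 1 member near Muc13, Parp14, its median was −1.69 over 48 members. Its members that fell, adjusted over the list alone, numbered from 32 with the retina covariate to 47 with quality weights (13 against WT 3 alone). The replicate numbers were not taken to pair the samples, since the deviations of same-numbered libraries correlated at r = 0.0904, 0.363 and 0.189, not all over 0.1. As a hint from the data and not the design, 5 of the 6 libraries correlated best with their own number, and WT 1 did so with KO 2 (0.180). With the number as a replicate block the count of genes was 0 (2529 at an unadjusted p under 0.05), that of lists was 23, the interferon median was −1.69, and Muc13 was at −1.89. Muc13 stayed below the wild type in each of the 11 alternatives run for it, from −2.55 to −1.41 when a library was left out.

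Of the 21 other lists past camera, 9 changed sign, 6 lost their call and 6 kept it with the retina covariate, and 8 medians changed sign without WT replicates 1 and 2. The 6 were basement membrane, macrophage, antigen presentation, cell proliferation, red blood cell, and cartilage and bone. Medians that changed sign, given first without WT replicates 1 and 2 and then with the retina covariate, were 0.168 and 0.0805 for the cornified envelope, −0.15 and −0.16 for corneal endothelium, 0.0395 and 0.0296 for pattern recognition, 0.0748 and 0.0402 for the EGF receptor family, 0.12 and 0.16 for oxidative phosphorylation, −0.00622 and −0.0124 for glycolysis, 0.66 and 0.72 for skeletal muscle, 0.0959 and 0.138 for the cytosolic ribosome, 0.12 and 0.0274 for mucins, 0.0352 and 0.0329 for O-glycosylation, −0.14 and −0.18 for keratocytes, 0.43 and 0.51 for mitochondrially encoded genes, −0.38 and −0.0916 for lens, and 0.31 and 0.36 for limbal epithelium. Retina itself was at −0.0718 with its own covariate, as the construction requires, and cytokines were at 0.15 without WT replicates 1 and 2. Genes that changed sign in the same order were Foxc1 (0.0912, 0.0807), Pycard (0.0220, 0.0296), Ndufa8 (0.00201, 0.0237), Pfkm (0.13, 0.14), Tnnc1 (0.44, 0.47), mt-Co1 (0.48, 0.55), Cryaa (−0.81, −0.50) and Muc1 (0.88, 0.71); Muc4 was at 0.0976 without WT replicates 1 and 2 and Aldh3a1 at 0.00343 with the covariate.

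Lists with no call that passed in an alternative were immediate early genes (3 settings) and genes near Muc13 (1), lens without KO 3 (1.65) or WT 1 (0.48), mitochondrially encoded genes without KO 3 (−0.65), and, with a median of the other sign, keratocytes without WT 1 and lens and keratocytes with the retina covariate. Oxidative phosphorylation, corneal endothelium, skeletal muscle and the ribosome passed with a median of the other sign with that covariate.

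With library size alone, O-glycosylation was at 0.12, cytokines at 0.16, mitochondrially encoded genes at 0.13, genes near Muc13 at 0.11 and limbal epithelium at 0.10, against a shift of all genes of 0.19. Cytokines were at 0.23 with no low-count filter. With quality weights, immediate early genes were at −0.0710, Wnt at −0.0914, Notch at −0.34 and Tgm1 at −0.14. Limbal epithelium was at 0.0284 with limma-voom and 0.0223 with the replicate block, Wnt at −0.0652 with the 1 CPM filter, and Notch at −0.00283 with DESeq2 size factors and −0.00037 with limma-voom. Glands also lost their call with no low-count filter and with the 1 CPM filter, corneal endothelium with limma-voom and the replicate block, and macrophage, complement, and cartilage and bone with quality weights. Leaving out 1 library gave medians from −0.78 to 0.51 for mucins and for Muc1, −0.32 to −0.0264 for O-glycosylation, 0.67 to 1.97 for neutrophils, −0.31 to 0.38 for cytokines, −0.11 to 0.63 for keratocytes, −0.65 to 0.34 for mitochondrially encoded genes, −3.01 to 3.68 for lens, −0.47 to 0.33 for limbal epithelium, −0.25 to 0.24 for Wnt and −0.19 to 0.10 for Notch, and values from −2.96 to 4.02 for Cryaa, −0.85 to 0.24 for mt-Co1 and −0.17 to 0.65 for Tgm1. The cause of these changes was not tested. Depth limits Muc13, Cxcl9 and Clec4d, with at most 22 counts per library.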

Other observations

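The tests of retinal carry-over, of a mislabelled library and of the causes of the interferon difference were chosen only after the results were seen; those of other splits and of the genes near Muc13 were chosen before. A predicted gene outside the rule for named genes, Gm14440 (chromosome 2, 175275125 to 175286805), had 56, 120 and 70 counts in KO 1 to 3 and 0 in each wild-type library, at least 23.04-fold higher against a floor of 3 counts per library, with shared reads. With Prb1 and Cxcl9 it made up the 3 tested genes at 0 in all libraries of 1 genotype. Of the 9 genes within 5 Mb of Muc13 whose groups did not overlap, Arhgap31 lay higher in the knockout and Cd80, Tmem39a, Fyttd1, Dtx3l, Acap2, Snx4, Parp14 and Parp9 lower; Dtx3l, Parp9 and Parp14 are known interferon-induced genes.

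Retina RNA was abundant in 4 of the 6 libraries, KO 1 to 3 and WT 3. A candidate explanation is retinal tissue carried over at dissection. That 31 of the 31 retina genes (100%) were higher in WT 3 than in both other wild-type libraries restates the pattern and adds no support to it. Of these genes 1 is in another list, and 3 were above 10 CPM in WT 1. WT 3 lay at the knockout level (median difference −0.0485 on the log2 scale over the list, SE 0.115), which restates the pattern too. If its label is right, retina RNA can be abundant in a cornea library without loss of Muc13, but this rests on 1 library. Whether WT 3 is a knockout library under a wrong label stays open, because its Muc13 counts are too few to decide. Its interferon-response genes lay 1.45 above the knockout mean (median, SE 0.137). Both SEs treat the members of a list as independent, although their estimated correlation was 0.938 for the retina list and 0.394 for the interferon list. The interferon difference was found with WT 3 counted as wild type, so it cannot decide the label of WT 3. Its Muc13 level of 0.561 CPM lies below the 95% intervals of WT 1 and WT 2 and inside those of KO 1 and KO 2, but above that of KO 3. However, the interval of WT 3 itself, 0.257 to 1.07 CPM, overlaps those of all other libraries. How the corneas were dissected stays open too.

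Interferon-response genes were lower in the knockout libraries, by 1.73 in mean log2 CPM. With 10 splits of 6 libraries no share under 0.05 can be reached; 1 of the 10, the real one, gave a difference as large, and the highest other was 0.969. With the retina content as a covariate the median was −1.34 (SE 0.135). Retina RNA was low only in WT 1 and WT 2, so this fit compares the knockout libraries mainly with WT 3. It therefore cannot settle whether dilution by retinal tissue plays a part. With the corneal epithelium content as a covariate the median was −1.88 (SE 0.182). WT 1 and WT 2 lay above every knockout library in this content (mean log2 CPM 10.4 and 10.3). WT 3, at 8.94, lay inside the knockout range of 7.25 to 9.40. At equal content this fit too compares the knockout libraries mainly with WT 3, so it cannot settle whether fewer epithelial cells play a part. The values argue against fewer macrophages and dendritic cells, whose markers had a median of 0.56 (SE 0.163). That last median ranged from 0.15 without WT 1 to 0.81 without WT 2 and so stayed above 0, but it is no firm measure of cell numbers. The SEs here treat the members of a list as independent, although their estimated correlation was 0.401 for the macrophage list and 0.394 for the interferon list. Loss of Muc13 may lower interferon signalling in the cornea, but housing, microbial exposure or the genetic background of the lines could do so too, and none of these was tested. The count of genes cannot be tested this way, since the real count of 0 by edgeR (656 at an unadjusted p under 0.05, 72 by DESeq2) is reached by 10 of the 10 splits whatever the data; the highest other was 0. At an unadjusted p under 0.05, 3 splits that mix the genotypes gave more genes than the real 656, namely 838, 2053 and 2222. The same 3 had more genes without overlap (2534, 3656 and 4861 against 1531, where chance gives 10%). This points to a structure of the samples other than genotype. In each of these 3 splits WT 1 and WT 2, the libraries with little retina RNA, were on the same side and WT 3 on the opposite side. For lists, 5 of the 10 splits gave at least the 22 lists of the real one, with 26 in the highest other, so camera with the preset correlation called many lists in splits that mix the genotypes.

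A knockout line can carry a flanking segment from another strain, which could set genes near Muc13 apart. Genes within 5 Mb separated the genotypes in 9 of 93 cases and other genes in 1522 of 14890 (Fisher's exact odds ratio 0.941, 95% interval 0.415 to 1.88, two-sided p = 1). The interval includes a near doubling, and with 9 separated genes a small segment cannot be told apart from none. The list of genes near Muc13, fixed in advance, had 45 tested members and is not the same set as these 93 genes. It passed camera in 1 alternative, without KO 1 (median −0.09, adjusted p = 0.0459, and 0.0459 to 0.758 over all alternatives).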
